A study of Mus musculus with 9 samples.

How the data were processed

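Total RNA of RAW 264.7 cells, a mouse macrophage line, was measured on 9 Affymetrix mouse expression arrays, 1 per sample. Per the labels, 3 samples were untreated, 3 were stimulated with bacterial lipopolysaccharide (LPS) at 100 ng/ml for 18 h, and 3 came from cells that constitutively overexpressed CstF-64. CstF-64, encoded by Cstf2, is a subunit of the cleavage stimulation factor, which takes part in forming the 3' ends of mRNAs. RNA was isolated with the Ultraspec system and a university core facility hybridised and scanned the arrays, per the labels. The expression construct, the kind of cell population and the nature of the replicates (separate cultures or repeated arrays of 1 RNA) are not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be technical.

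The deposited values are intensities, 1 per probe set and array, on a linear scale. The software, background correction and normalization that made them are not given in the sources used here. The deposited table holds 22690 probe sets, of which 64 are control probe sets. The values show that the arrays had been scaled to a common level: the mean after trimming 2% from each end lay between 150.05 and 150.06 in all 9 columns, while the medians lay between 42.75 and 54.2. No column repeated another, no value was negative and 38 were exactly 0. The number of arrays, 3 per group, limits the precision.

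Probe sets were named from a platform annotation table, with symbols updated through the gene identifier to those of the mouse assembly GRCm38.p6. Of 22626 probe sets tested, 20380 carried 1 gene, 691 several and 1555 none, and probe sets with several genes or none were not named. The named probe sets covered 12393 genes, 4956 of them with 2 or more probe sets. The chromosome of a gene was taken from the same gene table, and no coordinates were used.

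All choices in this paragraph were made before the data were examined. Values were kept as deposited because the trimmed means lay within a factor of 1.1 of each other. They were transformed to log2(intensity + 13), where 13 is 0.25 of the median intensity of all values, 50.2, rounded to a whole number. Log2 changes are on this scale, which understates the change of dim probe sets. One linear model with a mean for each group was fitted to all 9 arrays with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 22626 non-control probe sets, and the threshold was an adjusted p of 0.05. "Rose", "fell" and "called" refer to that threshold. Probe sets of 1 gene that changed unequally were sought with limma's diffSplice F test over the 4956 genes. Gene lists, 24 in number, were tested with camera at a preset inter-gene correlation of 0.01 on the brightest probe set of each gene, adjusted over the 24 lists, and members were also adjusted over the list alone. For the target gene, an exact permutation test of 3 against 3 arrays was run as well, whose smallest two-sided p is 0.1.

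Genes were named by a rule. For each comparison with untreated cells it took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, using the brightest probe set of each gene, and up to 4 members of every list by adjusted p, or 2 where fewer than 4 passed. It also took 5 genes each way for CstF-64 against LPS, up to 5 genes in each class of genes called in both comparisons, the 5 genes with the smallest p for unequal probe sets, and Cstf2 and Cstf2t always. Genes outside the rule are said to be so where they appear.

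The Bacillus control probe sets, 27 in number with a median intensity of 2.2, reached at most 31.2, and that value served as the background limit. Where all arrays of a group lay at or below 31.2, a fold is written as "at least N-fold": the geometric mean of the brighter group against 31.2.

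Because both comparisons with untreated cells use the same 3 untreated arrays, their overlap and correlation were set beside 100 simulations of unchanged groups sharing those controls and beside the overlap of independent lists. The fit was tested on simulated data in which 200 of 22626 probe sets were changed. In the simulated LPS comparison 10% of changes of 0.5 log2 units were called, 66% of 1 unit, 100% of 2 units and 98% of 3 units, with 6 false calls among 143. In the simulated CstF-64 comparison the shares were 12%, 64%, 100% and 100%, with 12 false calls among 150. For unequal probe sets, 95.5% of 200 genes with a simulated difference of 1.5 log2 units were recovered, with 17 false calls over 4956 genes. A simulated shift of the cell cycle list by -0.60 was called, and none of the other lists was. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called without a shift. In the data the estimated correlation was 0.496 for interferon-stimulated genes.

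Alternatives tried were quantile normalization, median centring, pseudocounts of 3 and 50, probe sets brighter than the median, eBayes without a trend or with a robust variance, a fit of only the groups compared, the replicate number as a block, an added limit of 2-fold, the Simes test, an estimated correlation for camera, the mean of a gene's probe sets, and leaving out each array in turn. Leaving out both LPS array 1 and CstF-64 array 1 was added after the data had been seen. The 2-fold limit was applied to counts only, not to the calls of single genes. Genes whose probe set was dimmer than the median have no result in the setting limited to brighter probe sets. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for tables and exact tests, and matplotlib 3.10.9 for figures. Neither probe sequences nor a genome was used here.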

Results

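Transcript levels were measured with 9 arrays in RAW 264.7 cells, a mouse macrophage line that responds to bacterial LPS: 3 untreated samples, 3 samples after 18 h with LPS at 100 ng/ml, and 3 samples labelled as constitutively overexpressing CstF-64. The comparisons ask what LPS changes, what differs in the samples labelled CstF-64, and which genes are called in both. No group is a control population for the construct. An effect of CstF-64 therefore cannot be separated here from other differences between the cell populations. Values are deposited intensities, given as mean ± SD over the 3 arrays of a group. Log2 changes and adjusted p-values come from limma. Array medians lay between 42.75 and 49.3 in the LPS group and between 51.1 and 54.2 in the other arrays. Within groups the arrays correlated at r = 0.965 to 0.989 across probe sets. LPS array 1, with a mean r of 0.966 to its own group, and CstF-64 array 1, with a mean r of 0.975, stood apart from the other 2 arrays of their groups. CstF-64 array 1 correlated with the untreated arrays at r = 0.976 to 0.981. The ratio of 3' to 5' signal, a sign of RNA quality, was 1.03 to 1.22 for actin and 0.79 to 0.88 for Gapdh over the 9 arrays.

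The transcript of CstF-64 itself was not higher in the arrays labelled CstF-64. The brighter probe set of Cstf2, 1419645_at, read 377.7 ± 18.0 in untreated cells (SD, n = 3), 358.0 ± 38.4 in the arrays labelled CstF-64 and 221.5 ± 26.1 after LPS. In the arrays labelled CstF-64 its log2 change was -0.08 (SE 0.13, limma adjusted p = 1.00, exact permutation p = 0.4). After LPS it fell by 0.74 on the log2 scale (SE 0.13, limma adjusted p = 0.0034, exact permutation p = 0.1, the smallest that 3 against 3 allows). The dimmer probe set, 1419644_at, read 116.3 ± 17.0 in untreated cells, 87.6 ± 8.57 in the arrays labelled CstF-64 and 118.7 ± 15.4 after LPS, with limma adjusted p = 0.763 and 0.940 and exact permutation p = 0.1 and 0.8 for the respective changes. All arrays labelled CstF-64 (80.4 to 97.1) lay below all untreated arrays (100.2 to 134.1) there. Cstf2t, a testis-type paralog of Cstf2, read 268.2 ± 13.5 in untreated cells, 260.3 ± 10.5 in the arrays labelled CstF-64 and 195.7 ± 31.4 after LPS. Its fall after LPS (log2 -0.44, limma adjusted p = 0.0456) was no longer called under 11 of 16 alternative settings, quantile normalization among them, with adjusted p over all alternatives from 0.0250 to 0.212. Among fits without a single array the call held only without LPS array 2. The construct is not given in the sources used here. Probe sets outside the expressed sequence would not register it, and whether these lie inside it is not known. The label is used here only as a name for those arrays.

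**Figure D1:**
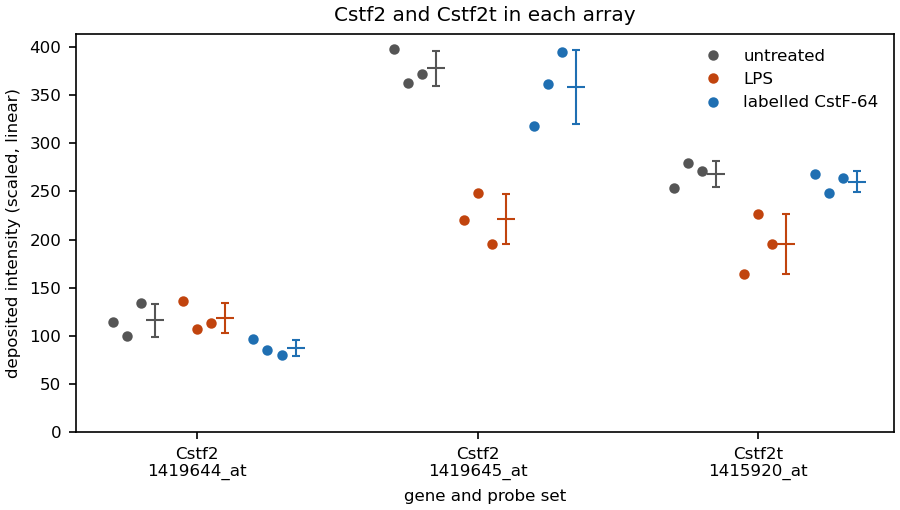
Deposited intensity (linear scale) of the 2 probe sets of Cstf2 and the probe set of Cstf2t in each of the 9 arrays. Points are arrays, coloured by group, with mean ± SD beside them. For probe set 1419645_at the LPS arrays lie between 195.9 and 248.1, below all untreated arrays and all arrays labelled CstF-64.

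After LPS, genes of inflammation rose and genes of cell division fell. Csf3, the granulocyte growth factor G-CSF, read 43.9 ± 43.1 in untreated cells and 3708 ± 1353 after LPS (SD, n = 3), a log2 change of 6.26 (limma adjusted p = 5.3e-05). Il1b, the cytokine interleukin-1 beta, went from 56.2 ± 39.7 to 3583 ± 960 (log2 5.81). The chemokine Ccl5 went from 70.6 ± 52.0 to 4438 ± 916 (log2 5.88) and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, from 57.3 ± 40.5 to 3994 ± 1909 (log2 5.88). Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose at least 51.6-fold to 1617 ± 200, and Socs3, a feedback inhibitor of cytokine signalling, at least 48.1-fold to 1501 ± 21.3. In the opposite direction, the mitotic genes Ube2c (1254 ± 161 to 87.7 ± 14.6, log2 -3.66), Ccnb2 (915 ± 62.9 to 65.1 ± 12.4, log2 -3.58) and Mki67 (1161 ± 134 to 92.8 ± 17.6, log2 -3.48) showed 3 of the 10 largest falls.

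The other genes with the largest rises were Ccl2, Acod1 and Cxcl2, with log2 changes from 5.47 to 5.85 and limma adjusted p from 0.000151 to 0.000315, and Il1a, which rose at least 24.8-fold (limma adjusted p = 0.000109). The other large falls were those of Kif2c, Cenpa, Ect2, Anln and Cdc20, which act in mitosis and cytokinesis, of Pole, a DNA polymerase subunit, and of Trem2, a macrophage receptor (808 ± 337 to 94.4 ± 74.4, log2 -3.28, limma adjusted p = 0.0083). LPS array 1 was the brightest of the LPS arrays for several inflammatory genes. Il1a read 1820, 425.7 and 601.3 in LPS arrays 1, 2 and 3, Ccl2 5118, 2002 and 2430.4, and Ptgs2 6193, 2758 and 3032. Untreated array 3 was the brightest untreated array for some of the same genes, with Cxcl2 at 296.9 against 41.1 and 65.9 and Acod1 at 188.4 against 18.1 and 64.8.

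Among the 31 measured inflammatory cytokines and chemokines, 19 rose and none fell (21 rose when adjusted over the list alone). Beyond those above, Ccl22, a chemokine for T cells, rose at least 2.39-fold to 74.8 ± 4.08. Of 38 interferon-stimulated genes, 29 rose and none fell (34 adjusted over the list alone). Among them were Irf7, a regulator of interferon genes (97.0 ± 23.5 to 2479 ± 105, log2 4.52), the nucleic acid sensor Zbp1 (at least 11.1-fold), Oasl2 (at least 12.8-fold) and Bst2 (log2 3.15). Of 27 NF-kappaB targets and feedback regulators, 19 rose and none fell (22 rose and 1 fell adjusted over the list alone). They included Nfkbiz (log2 3.89), Traf1 (log2 3.68) and the mitochondrial superoxide dismutase Sod2 (668 ± 94.9 to 3533 ± 362). Of 16 genes of nitric oxide, prostaglandin and arginine metabolism, 10 rose and none fell (10 adjusted over the list alone). They included the arginine transporter Slc7a2 (at least 6.45-fold), Ptges (log2 2.19) and Gch1, which makes a cofactor of nitric oxide synthase (log2 1.97). Camera called these lists higher than other genes, with adjusted p = 9.1e-18, 7.0e-31, 7.2e-19 and 1.1e-10 in the same order. With an estimated correlation the adjusted p were 0.0717, 0.0717, 0.0215 and 0.0241, so that the calls of the last 2 lists held. Without LPS array 1 the counts that rose were 19, 27, 18 and 9.

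Cell cycle genes fell most widely: of 57 measured, 47 fell and 1, the growth regulator Myc, rose (48 fell and 2 rose adjusted over the list alone). Birc5, which encodes the mitotic protein survivin, went from 446 ± 48 to 51.4 ± 8.76. The list lay lower than other genes (camera adjusted p = 7.0e-31) and the call held with an estimated correlation (adjusted p = 0.0241). Of 41 mRNA splicing genes, 23 fell and none rose (26 fell adjusted over the list alone). They included Sfpq (log2 -1.57), Mbnl1 (1655 ± 299 to 645 ± 99.4), the spliceosome core protein Prpf8 (log2 -1.0) and Snrpd3 (log2 -0.90). Of 35 genes of pre-mRNA 3' end processing, 9 fell and 2 rose (14 and 2 adjusted over the list alone). Casp8ap2 (log2 -1.26), Cstf2 and Pabpc4 (log2 -0.72) fell, and Lsm10, which acts on histone pre-mRNA, rose from 176 ± 17.2 to 297 ± 5.90. Both lists were called lower by camera (adjusted p = 1.5e-08 and 0.0012), and with an estimated correlation the adjusted p were 0.121 and 0.215. Of 5 replication-dependent histone genes measured, H1f2 (765 ± 34.3 to 1726 ± 470) and H2bc18 rose and H3c4 fell, the last call being lost under 8 of 15 alternative settings (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.380). Without untreated array 2, 15 splicing genes fell. Leaving out any one of the untreated and LPS arrays, 1 histone gene rose, and none fell except without untreated array 2 (1 fell).

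Genes of stress and metabolism moved in smaller numbers. In the oxidative stress list 7 of 19 rose and 1 fell (8 and 1 adjusted over the list alone). The cystine transporter Slc7a11 (log2 2.57), the autophagy receptor Sqstm1 (1107 ± 166 to 4783 ± 557) and the haem oxygenase Hmox1 (log2 1.99) rose, and Gclc, of glutathione synthesis, fell (log2 -1.32). In the list of unfolded protein and integrated stress response genes 7 of 32 rose and 1 fell (9 and 2 adjusted over the list alone). Ddit3 (77.9 ± 35.0 to 466 ± 88.9), Atf3 (log2 2.21) and Ppp1r15a (log2 1.55) rose and Atf6 fell (log2 -1.02). Of 27 genes of cholesterol synthesis and lipid efflux, 7 fell and 2 rose (8 and 2 adjusted over the list alone). Fasn, the fatty acid synthase (log2 -1.51), Dhcr7 (log2 -1.24) and Nsdhl (log2 -0.83) fell, and Plin2, a lipid droplet protein, rose from 895 ± 193 to 2709 ± 311. Of 22 glycolysis and hypoxia genes 3 rose and none fell (3 adjusted over the list alone), among them the glucose transporter Slc2a1 (1257 ± 168 to 2993 ± 886) and Pfkfb3 (log2 1.97, a call lost under 4 of 16 alternative settings). Over 19 genes of this list (Adm, Egln3 and Ndrg1 left out), LPS array 1 had the highest mean of the 9 arrays. It lay 0.40 log2 units above the genes' own means, against -0.00 and 0.06 in LPS arrays 2 and 3. Without LPS array 1, 2 genes of the list rose. Without untreated array 2 or LPS array 2 also 2 rose, and 1 without untreated array 1 or LPS array 3. Of 42 genes of mitochondrial respiration and the citric acid cycle, 7 fell and 1 rose (8 and 1 adjusted over the list alone). Among those that fell were Fh1 (log2 -0.94), Idh3g (log2 -0.71), Ndufs1 (log2 -0.69) and Mdh1 (log2 -0.68), the calls of Fh1 and Idh3g being lost under 1 and 2 alternative settings. Without untreated arrays 1 and 2 in turn, 3 and 4 genes of that list fell and none rose, and none rose without LPS array 2 or 3. Of the unfolded protein and integrated stress response list 3 genes rose without untreated array 2, and 2 fell without untreated array 1 or LPS array 1. The median change of the respiration list was -0.15 with the deposited scaling and 0.00 after median centring. Camera called the 5 lists (adjusted p = 0.00087, 0.0238, 0.0050, 0.0059 and 0.0484 in this order), and with an estimated correlation none was called (adjusted p = 0.0717, 0.158, 0.305, 0.486 and 0.642).

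Of 24 antigen presentation and costimulation genes 7 rose and 2 fell (12 and 2 adjusted over the list alone). Cd274, the ligand PD-L1 (65.3 ± 18.5 to 803 ± 197), Cd40 (log2 2.11), the peptide transporter Tap1 (log2 1.72) and Psme1 (log2 1.06) were among those that rose. Of 38 genes of macrophage identity and phagocytosis 9 rose and 6 fell (10 and 6 adjusted over the list alone). Cd36, a scavenger receptor for oxidised lipids, rose from 168 ± 44.3 to 1145 ± 123, and Cebpb (log2 2.12), Fcgr1 (log2 2.01) and Itgam (log2 1.48) also rose. Among 29 apoptosis regulators 7 rose and 3 fell (7 and 3 adjusted over the list alone). The rises included the TNF receptor Tnfrsf1b (151 ± 47.4 to 2797 ± 632), the death receptor Fas (at least 5.96-fold), Casp4 (log2 2.76) and Mdm2 (log2 1.56). Among 32 matrix, protease and motility genes 9 rose and 1 fell (10 and 1 adjusted over the list alone). Plaur (log2 2.64), Marcks (at least 3.03-fold) and Itga5 (log2 2.21) rose and Itga4 fell (log2 -1.88). Camera called these 4 lists higher (adjusted p = 5.6e-06, 0.0053, 0.0063 and 0.00018), and with an estimated correlation the adjusted p were 0.0764, 0.347, 0.0717 and 0.253. Of 27 genes of LPS sensing and Toll-like receptor signalling 5 rose and none fell (5 adjusted over the list alone), namely Ikbke (log2 1.76), Tbk1 (log2 0.77), Cd14 (3408 ± 545 to 5938 ± 623), Map3k8 (log2 0.58) and Tollip, and the list was not called (camera adjusted p = 0.0901). In that list 2 rose without untreated array 1, 3 without untreated array 2 or 3, and 3 rose and 1 fell without LPS array 1. The calls of Cd14 and Map3k8 were lost under 2 and 8 of 16 alternative settings. Of 29 lysosomal genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.134). The protease Ctsl (2166 ± 178 to 4386 ± 216) and Npc2 (log2 0.69) rose and Man2b1 (log2 -0.69) and Tfeb (log2 -0.61) fell. The call of Ctsl was lost under 1 and that of Tfeb under 10 of 16 alternative settings. Leaving out any one of untreated arrays 1, 2 and 3 and LPS arrays 1 and 3, 2 lysosomal genes rose and 1 fell. In the antigen presentation list 1 fell when any of these arrays or LPS array 2 was left out, except untreated array 1, and of the apoptosis regulators 1 fell without untreated array 1 or 2.

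No cytosolic ribosomal protein gene of 35 was called (0 adjusted over the list alone). Rpl13a read 3193 ± 303 in untreated cells and 4001 ± 398 after LPS (limma adjusted p = 0.114), and Rpl12 105.5 ± 24.5 and 62.8 ± 14.3 (limma adjusted p = 0.0574). The list as a whole was called higher by camera (median log2 0.19, adjusted p = 0.0013), had an adjusted p = 0.486 with an estimated correlation, and turned to a median of -0.10 under quantile normalization. Of the lists for other cell types, the osteoclast list had 2 of 11 genes up (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.378), Acp5 (82.1 ± 24.4 to 268 ± 22.8) and Tcirg1 (log2 0.64, lost under 7 of 16 alternative settings). The granulocyte and mast cell list had 3 of 19 up (3 adjusted over the list alone, camera adjusted p = 0.0042, and 0.170 with an estimated correlation), among them Lcn2 and the histidine decarboxylase Hdc (at least 2.54-fold). In the fibroblast and endothelial list 1 of 20 rose, Dcn (at least 1.48-fold; 1 adjusted over the list alone, camera adjusted p = 0.321), while Acta2 read 100.0 ± 13.0 and 160 ± 58.1 (limma adjusted p = 0.114). None of 22 lymphocyte markers was called (0 adjusted over the list alone, camera adjusted p = 0.548). For that list the mean change was -0.01 and the median 0.04, and 2 genes fell without LPS array 1 and 1 without untreated array 2. In the osteoclast list 1 rose without untreated array 1 or 3 or any single LPS array, and 1 fell without untreated array 2 or LPS array 1. In the fibroblast and endothelial list 1 fell without untreated array 1.

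**Figure D2:**
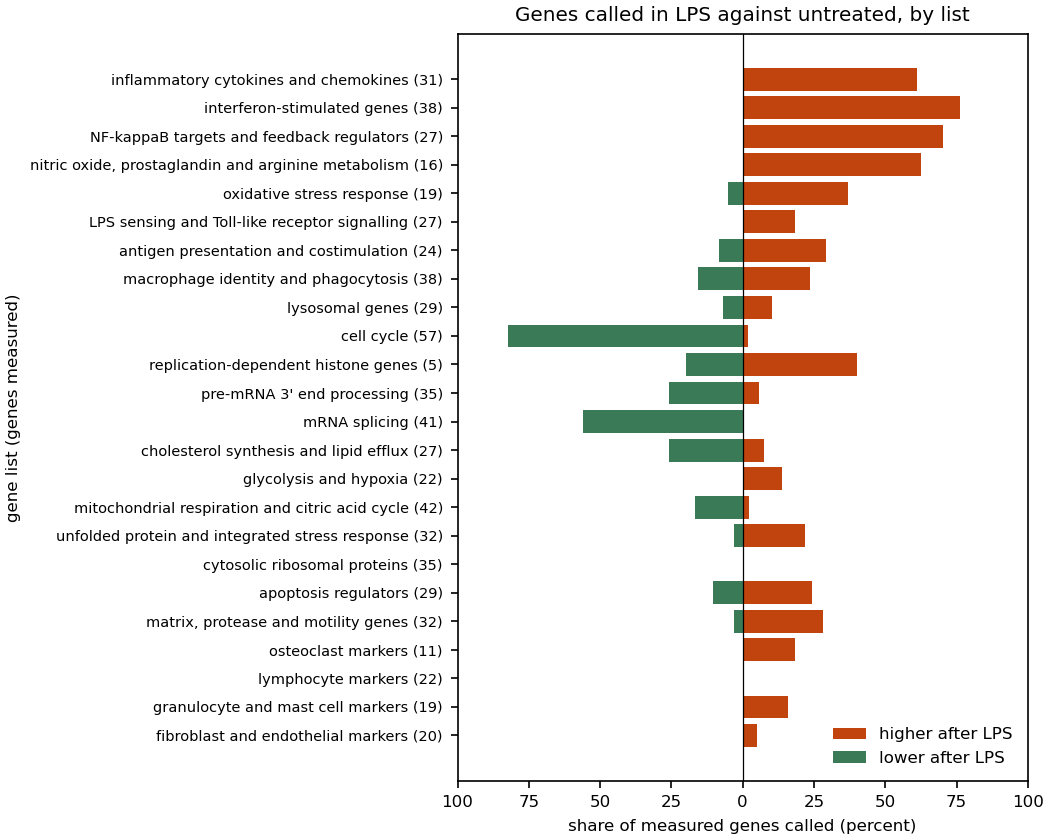
Share of the measured genes of each of the 24 lists (percent, horizontal axis) called higher (right) or lower (left) after LPS at a limma adjusted p of 0.05, with the number of genes measured in parentheses. Of 38 interferon-stimulated genes 29 rose, and of 57 cell cycle genes 47 fell.

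Some members that complete small counts were named after their values were seen: Tollip, Myc, H2bc18 and, not given above, H2-DMa and Ifi30 (antigen presentation) and Aifm1, Bid and Casp2 (apoptosis), which fell, and Abca1 (lipid efflux), Hif1a (hypoxia), S100a8 (granulocyte), Npc1 (lysosome), Ndufs3 (respiration) and Ssu72 (3' end), which rose. Of 101 named genes called after LPS, 89 were called under every alternative setting run for them, the 2-fold limit not being among these. Single arrays decided 10 of the others: Cd14, Cstf2t, H3c4, Idh3g, Map3k8, Pfkfb3, Tcirg1 and Tfeb lost the call without untreated array 1, Cd109 and Fh1 without untreated array 2, and between 4 and 8 of the 10 did so without any single untreated or LPS array, with limma adjusted p up to 0.142.

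In all, 3755 of 22626 probe sets were called between LPS and untreated cells, 1341 higher and 2414 lower, covering 2560 named genes. Of these, 611 rose and 940 fell at least 2-fold. The values of the groups did not overlap for 3748 of the called probe sets, and for 33.4% of all probe sets where 10% would be so by chance. The camera test called 18 of 24 lists with the preset correlation and 3 with an estimated one. The split depended on the scaling: 35.7% of calls were higher with the deposited values, 46.2% after quantile normalization (1528 higher, 1780 lower) and 60.5% after median centring (2228 higher, 1455 lower), which moved the median change of all probe sets from -0.04 to 0.12. Scaling to the hybridisation controls, tried after the results were seen, moved that median the other way, to -0.21. No calls were made on that scale. Without untreated array 2 the count was 2399, of which 2338 were among the 3755. After median centring 2796 of the 3755 were called again. The named genes were chosen mostly for large changes or small adjusted p. How often they held therefore does not measure the stability of all calls.

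In the arrays labelled CstF-64, few genes differed from untreated cells. Cd36, the scavenger receptor, read 168 ± 44.3 in untreated cells and 6.13 ± 4.95 in the arrays labelled CstF-64 (SD, n = 3), at least 5.24-fold lower (limma adjusted p = 0.00061). Eif2s3y, a translation initiation factor gene of the Y chromosome, went from 149 ± 28.3 to 5.30 ± 4.03, at least 4.72-fold lower (limma adjusted p = 0.00043). Rbpms, an RNA-binding protein gene, rose at least 4.75-fold, from 6.37 ± 0.777 to 151 ± 31.1 (limma adjusted p = 0.00035). Plod2, a lysyl hydroxylase that modifies collagen, rose from 42.6 ± 14.7 to 476 ± 204 (log2 3.06, limma adjusted p = 0.0141), with 241, 600 and 587.8 in CstF-64 arrays 1, 2 and 3. Rarb, the retinoic acid receptor beta, rose from 46.2 ± 2.17 to 235 ± 64.6 (log2 2.03, limma adjusted p = 0.0045).

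Among named genes, the other large rises were those of Mmp12, a macrophage elastase (at least 2.05-fold to 64.2 ± 4.44), Ambp (at least 1.78-fold to 55.7 ± 2.30), Trem3 (log2 1.36), the reductase Cbr4 (403 ± 21.1 to 1016 ± 97.3), Akap2 (at least 1.84-fold), Epsti1 (log2 1.09) and Lgals9, which encodes galectin-9 (104 ± 13.9 to 219 ± 22.4). The other large falls were those of B3galnt1 (at least 3.32-fold), the acyl-CoA thioesterase Acot1 (111 ± 4.18 to 17.0 ± 4.61, at least 3.57-fold), the Y-linked histone demethylase Kdm5d (at least 2.71-fold), Cd109 (at least 2.63-fold), Morc4 (at least 1.34-fold), the actin-associated genes Svil (149 ± 3.62 to 37.0 ± 7.15) and Trip6 (375 ± 53.8 to 111 ± 21.2), and Lpar1, a receptor for lysophosphatidic acid (125 ± 4.34 to 33.0 ± 4.10). All 56 called probe sets had no overlap between the groups. Of 25 named genes called, 9 were called under every alternative setting run for them: Acot1, Ambp, Cbr4, Cd36, Eif2s3y, Lpar1, Rarb, Rbpms and Svil. For Acot1, Ambp and Rbpms there were 15 such settings and for the others 16. The other 16, Plod2, Mmp12, Kdm5d and Lgals9 among them, lost the call in at least 1 fit without a single array: 10, 16 and 10 without untreated arrays 1, 2 and 3, and 2, 13 and 14 without CstF-64 arrays 1, 2 and 3, with limma adjusted p up to 0.201.

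**Figure D3:**
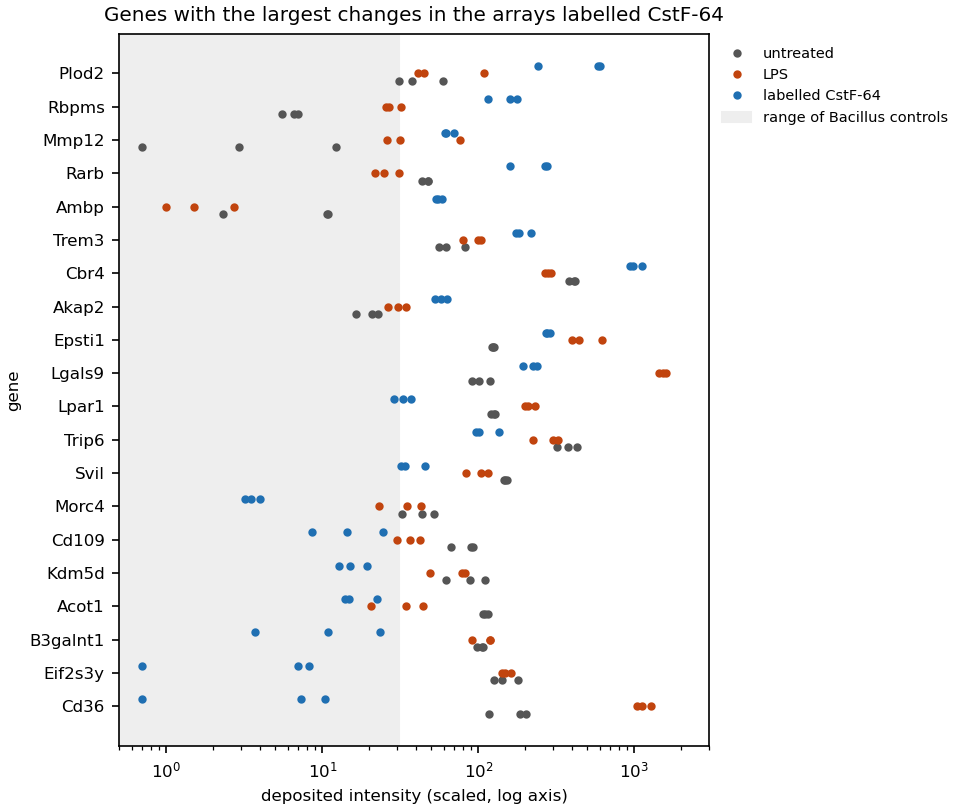
Deposited intensity (log axis) in each of the 9 arrays for the 10 named genes with the largest rise and the 10 with the largest fall in the arrays labelled CstF-64 against untreated arrays. Points are arrays, coloured by group, and the grey band reaches up to 31.2, the highest value of the Bacillus controls. Cd36 lies between 0.7 and 10.4 in the arrays labelled CstF-64 and between 1036 and 1278 after LPS.

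Of the 24 lists, 2 had a called member in this comparison: Cd36 fell among the 38 macrophage genes (2 fell adjusted over the list alone) and Mmp12 rose among the 32 matrix, protease and motility genes (2 rose and 1 fell adjusted over the list alone). The macrophage marker Adgre1, which encodes F4/80, read 511 ± 95.9 in untreated cells and 221 ± 10.7 in the arrays labelled CstF-64 (limma adjusted p = 0.0777), and the matrix protease inhibitor Timp2 177 ± 41.6 and 83.0 ± 21.1 (limma adjusted p = 0.279). Adjusted over the list alone, 2 genes also rose in the unfolded protein and integrated stress response list, and 1 gene each fell in the cytokine and osteoclast lists; none did in the other 19 lists. With all genes in the adjustment, without CstF-64 array 1 there were 2 macrophage genes, 1 cytokine gene and 1 matrix gene that fell. No gene of the matrix list rose without untreated array 1 or 2 or any single CstF-64 array, and 1 gene of the stress response list rose without untreated array 1. Camera called 4 lists higher than other genes: unfolded protein and integrated stress response genes (27 of 32 higher, median log2 0.27, adjusted p = 0.00046), glycolysis and hypoxia genes (21 of 22 higher, median log2 0.23, adjusted p = 0.0010), interferon-stimulated genes (27 of 38 higher, median log2 0.19, adjusted p = 0.0477) and NF-kappaB targets (23 of 27 higher, median log2 0.13, adjusted p = 0.0477). With an estimated correlation none was called (adjusted p = 0.167, 0.957, 0.972 and 0.957). In the stress list Ddit3 read 77.9 ± 35.0 in untreated cells and 211 ± 56.0 in the arrays labelled CstF-64 (limma adjusted p = 0.147), and Herpud1 184 ± 9.19 and 310 ± 31.4 (limma adjusted p = 0.105). In the glycolysis and hypoxia list Vegfa read 184 ± 11.5 and 410 ± 176 (limma adjusted p = 0.704) and Pfkl 960 ± 121 and 1368 ± 291 (limma adjusted p = 0.628). CstF-64 array 1 lay apart in this list, with Vegfa at 209.3 against 487.3 and 534.5 in CstF-64 arrays 2 and 3. Its mean over 19 genes of the list (Adm, Egln3 and Ndrg1 left out) was -0.23 against 0.21 and 0.19. Over the same 19 genes the untreated arrays had means of -0.35, -0.28 and -0.01, so that array 1 lay within their range.

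In lists without a called gene, the members named by the rule did not pass the threshold. In the cytokine list Cxcl16 read 383 ± 92.7 in untreated cells and 161 ± 18.3 in the arrays labelled CstF-64 (limma adjusted p = 0.155) and Ccl22 2.83 ± 1.17 and 9.47 ± 2.23, within background. Among interferon-stimulated genes Usp18 read 88.3 ± 29.0 and 183 ± 60.7 and Samhd1 424 ± 14.3 and 289 ± 14.2 (limma adjusted p = 0.403 and 0.310). Among NF-kappaB targets Nfkbiz read 47.9 ± 6.73 and 104 ± 40.5 (limma adjusted p = 0.572) and Traf1 29.6 ± 4.40 and 51.0 ± 15.5. For antigen presentation Cd86 read 20.3 ± 3.51 and 37.5 ± 2.83 and Tap2 125 ± 18.6 and 83.4 ± 9.03, and for the cell cycle Mcm4 602 ± 109 and 421 ± 103 and Birc5 446 ± 48 and 630 ± 16.4. In 3' end processing Cpsf2 read 283 ± 53.5 and 201 ± 28.0 (limma adjusted p = 0.608) and Lsm10 176 ± 17.2 and 226 ± 21.2, and in splicing Dhx15 1106 ± 67.8 and 881 ± 95.9. The 20 lists not called had camera adjusted p from 0.0973 (cell cycle) to 0.991. Median, mean and test differed in sign for the antigen presentation list (median 0.03, mean -0.00), the histone list (median 0.04, mean -0.03) and the fibroblast and endothelial list (median -0.00, mean 0.01).

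In all, 56 of 22626 probe sets were called between the arrays labelled CstF-64 and untreated arrays, 23 higher and 33 lower, covering 40 named genes and 7 unnamed probe sets. At an unadjusted p of 0.05 there were 1460, somewhat above the share of 0.05 given by chance. Groups did not overlap for 12.9% of all probe sets where 10% would be so by chance. The count depended on single arrays: it was 18 without untreated array 2, 28 without untreated array 3, 24 and 20 without CstF-64 arrays 2 and 3, 85 without LPS array 1, which changes only the estimate of the spread, and 110 without CstF-64 array 1. The number of lists called was 2 without untreated array 2 or CstF-64 array 3 and 6 without untreated array 3 or CstF-64 array 1. Without both LPS array 1 and CstF-64 array 1, the arrays that stood apart, 286 probe sets were called. Of the 56, 16 were called again without untreated array 2, 20 without CstF-64 array 3 and 51 without CstF-64 array 1.

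Of the 56 probe sets called in the arrays labelled CstF-64, 23 were also called after LPS, 15 in the same direction and 8 in the opposite one. Galectin-9 gene Lgals9 rose in both, from 104 ± 13.9 in untreated cells to 219 ± 22.4 in the arrays labelled CstF-64 and 1523 ± 82.3 after LPS (SD, n = 3), as did Epsti1 (124 ± 1.82, 278 ± 7.88 and 487 ± 118 in the same order), Mmp12 and Rbpms, the last reaching 28.2 ± 3.35 after LPS, a mean within background. Acot1 (111 ± 4.18, 17.0 ± 4.61 and 33.1 ± 12.0), Cd109 and Ly86 (806 ± 67.1, 385 ± 55.6 and 489 ± 52.1), which encodes the LPS receptor homologue MD-1, fell in both. Abcd2 (25.5 ± 4.65, 6.73 ± 3.71 and 2.5 ± 0.6) and Tnfrsf17 (27.4 ± 6.58, 4.07 ± 3.55 and 4.17 ± 3.23) were also called lower in both, with every mean within background. Cd36 and Lpar1 fell in the arrays labelled CstF-64 and rose after LPS, as did Rgl1, an exchange factor for Ral GTPases (133 ± 2.77, 50.5 ± 11.3 and 747 ± 116). Sorl1, a sorting receptor (235 ± 15.0, 445 ± 54.6 and 68.2 ± 9.21), and Cbr4 (403 ± 21.1, 1016 ± 97.3 and 279 ± 11.5) rose in the arrays labelled CstF-64 and fell after LPS. The call of Cbr4 after LPS was lost under 1 of 16 alternative settings (limma adjusted p up to 0.0814).

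Independent lists of these sizes would share 9.29 probe sets, 4.88 in the same direction and 4.41 in opposite ones, and unchanged groups simulated against the same untreated arrays shared 0. Without any effect almost nothing is called, so that 0 follows from the simulation and is no measure for the 23. Across all probe sets, which are not independent replicates, the changes correlated at Pearson r = 0.28 and Spearman rho = 0.35, against 0.40 and 0.38 in those simulations. The simulated groups had no LPS effect, and such an effect can lower the correlation by widening the LPS changes. The lower observed values therefore do not show less likeness than chance. The covariance was 0.0425 against a simulated 0.0159, a difference of 0.0266, and the spread of the untreated arrays alone would give 0.0189 in place of 0.0159. With 3 untreated arrays the controls cannot be split, and part of the overlap may come from using them in both comparisons. The shared count was 9 without untreated array 2, 10 without untreated array 3, 36 without LPS array 1, 9 without either CstF-64 array 2 or 3 and 45 without CstF-64 array 1, and 129 without both LPS array 1 and CstF-64 array 1. Of the genes named here, only Acot1, Cbr4, Cd36, Lpar1 and Rbpms were called in the arrays labelled CstF-64 under every alternative run for them.

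**Figure D4:**
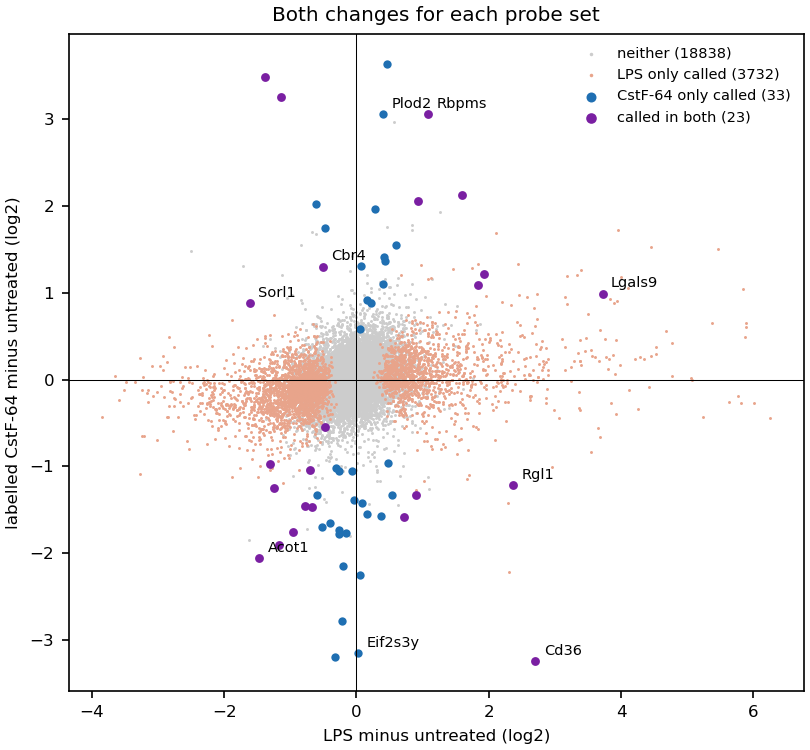
Log2 change in the arrays labelled CstF-64 (vertical axis) against log2 change after LPS (horizontal axis), both against untreated arrays, for each of the 22626 probe sets. Colours mark probe sets called in neither comparison (18838), after LPS only (3732), in the arrays labelled CstF-64 only (33) or in both (23). Most LPS calls spread along the horizontal axis, and Cd36 lies at 2.71 on it and -3.24 on the vertical one.

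Set against the LPS arrays directly, the arrays labelled CstF-64 lacked the inflammatory signal and kept that of dividing cells. Csf3 read 24.2 ± 16.6 in the arrays labelled CstF-64 and 3708 ± 1353 after LPS (SD, n = 3; log2 -6.70, limma adjusted p = 3.7e-05), Il1b 39.0 ± 5.94 and 3583 ± 960 (log2 -6.08), Acod1, which makes itaconate, 68.5 ± 59.8 and 4302 ± 303 (log2 -5.96), and Lcn2 and Cd36 were at least 51.6-fold and 36.6-fold lower. Ube2c read 1283 ± 74.8 and 87.7 ± 14.6 (log2 3.69), Trem2 907 ± 177 and 94.4 ± 74.4 (log2 3.53) and Mki67 1140 ± 110 and 92.8 ± 17.6 (log2 3.45), and Kif2c was at least 9.54-fold higher and Ccnb2 higher by log2 3.35. Cstf2 (1419645_at) was higher than after LPS (log2 0.66, limma adjusted p = 0.0066), while 1419644_at was lower and not called (87.6 against 118.7, log2 -0.39, limma adjusted p = 0.136). Of 57 cell cycle genes 45 were higher and 1 lower (48 and 1 adjusted over the list alone), of 38 interferon-stimulated genes 29 were lower (32 adjusted over the list alone), of 31 cytokines and chemokines 20 were lower (22 adjusted over the list alone), and of 41 splicing genes 20 were higher (25 adjusted over the list alone; 10 without LPS array 3 and 12 without CstF-64 array 3). In all, 3443 probe sets were called, 2133 higher and 1310 lower, and 50 of the 56 probe sets called against untreated arrays were also called against the LPS arrays. Camera called 15 lists with the preset correlation and 4 with an estimated one: NF-kappaB targets (adjusted p = 0.0210), nitric oxide, prostaglandin and arginine metabolism (adjusted p = 0.0210), cell cycle (adjusted p = 0.0266) and apoptosis regulators (adjusted p = 0.0481). Median, mean and test differed in sign for glycolysis and hypoxia (median 0.02, mean 0.03, test lower), unfolded protein and integrated stress response (median 0.15, mean -0.03) and lymphocyte markers (median 0.04, mean 0.06, test lower). After median centring 1249 probe sets were higher and 2097 lower, and the count was 2163 and 2093 without CstF-64 arrays 2 and 3.

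The probe sets of 1 gene were compared with each other. Their positions in the transcripts were not looked up, so an unequal change shows nothing here about the choice of 3' end. After LPS they changed unequally in 277 of 4956 genes with 2 or more probe sets (898 at an unadjusted p of 0.05). The 5 genes with the smallest adjusted p were Cp (2.9e-12), Kif2c (2.0e-10), Foxm1 (5.5e-09), Cdca3 (2.1e-07) and Top2a (2.8e-07). For Cp, the plasma ferroxidase ceruloplasmin, all 7 probe sets had an untreated mean within background. After LPS the brightest read 154 ± 43.9, while the probe set with the smallest change read 1.90 ± 0.458 and 1.57 ± 0.252, within background. For Top2a, a topoisomerase of dividing cells, 1454694_a_at fell from 1123 ± 60.7 to 158 ± 44.4 while the other probe set read 1.60 ± 0.361 and 1.57 ± 0.231. For Kif2c, 1437611_x_at fell at least 10.4-fold, to within background, and 1454221_a_at from 172 ± 6.88 to 66.7 ± 8.20. In the arrays labelled CstF-64, 132 of 4956 genes had an unadjusted p under 0.05, fewer than the share of 0.05 given by chance. After adjustment 2 genes passed, Cd36 and Lpar1 (limma adjusted p = 0.0491 each). Every probe set of both genes read lower than in untreated cells: for Cd36 the untreated means were 168, 60.5 and 15.9, the last within background, and those in the arrays labelled CstF-64 6.13, 1.47 and 4.80, all within background. For Lpar1 they were 125, 28.6 and 27.6 in untreated cells, the last 2 within background, and 33.0, 3.47 and 18.9 in the arrays labelled CstF-64. The background limits how far the dimmer probe sets can fall. The next were Rbpms (adjusted p = 0.184), Kdm5d (0.295) and Egfl7 (0.350). No gene passed after median centring, with a robust variance, with the Simes test or among probe sets brighter than the median (0 each). None passed without any of untreated arrays 2 and 3 or CstF-64 arrays 2 and 3. In turn, 1 passed without untreated array 1 or CstF-64 array 1, and 20 passed without both LPS array 1 and CstF-64 array 1. The LPS count was 157, 114 and 137 without untreated array 1, 2 or 3 and 125 among probe sets brighter than the median.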

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

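All tests in this part were chosen only after the result was seen. Of 37 control probe sets outside the comparisons, looked at in 2 groups, 5 read higher in every array of a group than in every untreated array and above the background limit, all 5 in the LPS group. By chance 3.7 would read higher over both groups, 1.85 in each, before the background limit is applied. The mouse actin 3' probe set read 4860 ± 477 in untreated arrays and 5847 ± 555 in LPS arrays (SD, n = 3), a ratio of 1.2, and the B2 repeat probe set 261 ± 57.4 and 429 ± 79.0, a ratio of 1.64. Both measure RNA of the cells. The hybridisation controls bioB-M (163 ± 12.7 and 203 ± 17.6, ratio 1.243), bioC-5 (292 ± 15.1 and 334 ± 25.6, ratio 1.14) and P1-cre-3 (4854 ± 621 and 6012 ± 628, ratio 1.239) are added to every array. The exact permutation p was 0.1 for each, the smallest that 3 against 3 allows. The actin ratio lay within the range of the ratios of the hybridisation controls. Over 18 hybridisation control probe sets the median level was 0.18 log2 units higher in LPS arrays than in untreated arrays. No biological explanation was tested.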

How the results depend on the processing

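Leaving out both LPS array 1 and CstF-64 array 1 was chosen only after the result was seen; the other tests here were planned. Of 137 results for named genes past the threshold, over the 3 comparisons, none changed direction under any alternative: of 2168 alternative values 2022 stayed past it and 146 did not. These genes were named mostly for large changes or small adjusted p, so these counts do not measure the stability of all calls. The 2-fold limit was not applied to single genes. The fit of only the groups compared was not run for the Cstf2 probe sets against untreated cells. Under all alternatives that were run, the fall of Cstf2 (1419645_at) after LPS and its higher level in CstF-64 against LPS stayed past the threshold. The other changes of the Cstf2 probe sets against untreated cells stayed on the other side of it under all, but 2 changed sign: 1419644_at after LPS, from 0.03 to -0.0639 without untreated array 2 and -0.0646 without LPS array 1, with or without CstF-64 array 1, and 1419645_at for CstF-64, from -0.08 to 0.00083 without CstF-64 array 1, with or without LPS array 1. Where values below differ, the cause was not tested, except that an added fold limit lowers a count by construction.

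With the added 2-fold limit, 1551 of 3755 probe sets remained for LPS, 1419 of 3443 for CstF-64 against LPS, and 11 of 23 called in both comparisons (7 of 15 in the same direction). With the replicate number as a block, 32 were called for CstF-64 in place of 56, 31 of them among the 56, 15 in both comparisons in place of 23 (8 in the same direction in place of 15), and 0 genes had unequal probe sets. The array numbers show no pairing, with same-number correlations from -0.06 to 0.16 against -0.24 to 0.20 for other pairs. Without both LPS array 1 and CstF-64 array 1, 286 were called for CstF-64, 129 in both (81 in the same direction), 20 genes had unequal probe sets and 7 lists were called, while the correlation of the changes was 0.21.

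The genes with unequal probe sets after LPS, 277, were 125 among probe sets brighter than the median. For CstF-64 the 2 genes became 0 with median centring, probe sets brighter than the median, the Simes test and a robust variance, 1 with a pseudocount of 3 and 6 with a pseudocount of 50. With a pseudocount of 50, 2 lists were called for CstF-64 in place of 4. With an estimated correlation 3 lists were called for LPS in place of 18, 0 for CstF-64 in place of 4 and 4 for CstF-64 against LPS in place of 15. Quantile normalization reversed the ribosomal protein list, from a median of 0.19 to -0.10 after LPS and from -0.12 to 0.12 for CstF-64 against LPS.

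Leaving out 1 array of the groups compared at a time gave 2399 to 3485 calls for LPS (4118 without CstF-64 array 1, which enters that comparison only through the spread), 18 to 110 for CstF-64, 2093 to 3299 for CstF-64 against LPS, 9 to 45 in both (3 to 24 in the same direction), a correlation of 0.22 to 0.36, 114 to 284 genes with unequal probe sets after LPS and 0 to 1 for CstF-64, and 2 to 6 lists for CstF-64. The fit without a variance trend was not run for unequal probe sets, whose test has no trend. Signal at or below 31.2 is background, so that falls to it are lower bounds and changes among dim probe sets are understated.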

Other observations

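The genes in the next paragraph were chosen after their values were seen, and all tests of explanations below were chosen only after the result was seen except that of brightness for the splicing genes. The counts over other splits of the arrays were also added after the results were seen.

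Several genes called in the arrays labelled CstF-64 fell outside the naming rule. The Y-linked demethylase gene Uty fell at both called probe sets (at least 2.07-fold and 1.90-fold). The leukocyte surface gene Cd99 fell at 2 probe sets (log2 -1.55 and -1.43), as did the growth factor receptor gene Fgfr1 (at least 1.53-fold and 1.81-fold). Falls were also called for Evl (at least 2.92-fold) and Eps8 (log2 -1.33), which act on actin, for the sialyltransferase gene St3gal6 (log2 -1.46), the phospholipid transfer protein gene Pltp (log2 -1.05), Olfm1 (log2 -1.02) and the protease gene Capn2 (log2 -0.97). Lamb2 also fell, with every group mean within background. Rises were called for the lipid phosphatase gene Plpp3 (at least 1.81-fold), Vopp1 (at least 1.26-fold) and, within background, Gabra3, Nrgn and Frk. A further probe set of Plod2 rose by log2 3.64.

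Genes of the Y chromosome were lower in the arrays labelled CstF-64: 4 probe sets of Eif2s3y, Kdm5d and Uty were called, with no CstF-64 value above 19.3 and no untreated value below 47.7. Array scaling is argued against, since the smallest fall was -1.36 log2 units under quantile normalization and median centring, and so is a female line that expresses Xist, whose brightest probe set changed by -0.0227. Cells without a Y chromosome are a candidate explanation that cannot be told apart from a lower level of these transcripts. Of the 7 named Y-linked probe sets above background in all untreated arrays, 5 were within it in all CstF-64 arrays, and the others were not. Tspy-ps read 38.2 to 46 in untreated arrays and 46.1 to 52.2 in CstF-64 arrays, and a probe set of Uba1y 31.5 to 34.1 and 30.6 to 45, so that neither fell. Whether these 2 measure the Y-linked transcript or background above the limit was not tested. Unnamed probe sets have no chromosome here and were left out of these counts. Of the 7 unnamed probe sets called for CstF-64, those falling from 209 to 12.0, 112 to 5.53 and 61.0 to 4.03 were not called after LPS. A further one fell from 134 to 26.6 and was also called lower after LPS. The rest rose, from 29.5 to 101, from 24.3 to 370 (log2 3.26) and from 48.4 to 721 (log2 3.49). The rises to 370 and 721 were larger than that of Rbpms, and both probe sets were called lower after LPS. Whether any unnamed probe set is Y-linked was not looked up. An effect of CstF-64 on the Y-linked genes was not tested.

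CstF-64 array 1 lay apart from CstF-64 arrays 2 and 3 by at least 2 log2 units at 27 probe sets at which the other arrays lay within 0.5, limits chosen after the arrays were seen; 11 were higher in array 1 and 16 lower. Adm, a hypoxia-induced peptide gene, read 86.5, 898.7 and 952.9 in CstF-64 arrays 1, 2 and 3, the cytokine antagonist gene Il1rn 1265, 94.7 and 97.2 and the transferrin receptor gene Tfrc 732.2, 98.0 and 112.9. Untreated cells mixed into array 1 are argued against, since the called Y-linked probe sets reached at most 8.31% of the untreated level where the pattern needs a median of 118% over the 15 of 27 probe sets with the untreated level on that side, and so are LPS-stimulated cells, since the 10 genes with the largest rise reached at most 9.89% of the LPS level where it needs 113% over the 21 with the LPS level on that side. A difference in oxygen supply may contribute: without the pattern's members, 19 genes of the glycolysis and hypoxia list lay at a mean of -0.43 log2 units in array 1 against arrays 2 and 3, with 15 lower, where the lowest random list of like brightness lay at -0.27. Those not lower were Ldha, Pkm, P4ha1 and Slc16a3. Random lists do not carry the correlation among the genes of this list, estimated at 0.395, so that comparison gives no p-value. Untreated arrays differed in the same way: over the same 19 genes their means were -0.35, -0.28 and -0.01. Adm, left out of these means, read 90.6, 142.9 and 339.1. CstF-64 array 1, at -0.23, lay within that range, and arrays 2 and 3, at 0.21 and 0.19, above it. The oxygen supply is a hypothesis found and tested on the same arrays, and no label gives culture conditions per sample.

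Splicing genes were lower after LPS, with a list median of -0.56 and 23 of 41 genes called, 15 without untreated array 2. The camera call was lost with an estimated correlation (adjusted p = 0.121). Array scaling is argued against, since the median nearest to 0 was -0.40 over quantile normalization, median centring and scaling to the hybridisation controls. A general fall of bright probe sets is argued against as well: the list lay at percentile 0 of 10000 random lists of like brightness, the lowest of which had a median of -0.41. Random lists do not carry the correlation among splicing genes, so that rank is no p-value for the list. Slower division of LPS-treated cells was not tested and stays open beside an effect of LPS itself.

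With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3755 calls for LPS, 56 for CstF-64 and 3443 for CstF-64 against LPS (1 of 10 splits as large in each), where the highest of the others gave 0, 0 and 1. For unequal probe sets the real counts of 277 and 2 stood against a highest other of 1 each (1 of 10 splits as large in each). Every other split mixes the groups compared, which puts their difference into the spread. Low counts there follow from that mixing and are no evidence for the real counts. For lists called, the real 18, 4 and 15 stood against a highest other of 19, 10 and 15, with 2, 8 and 2 of 10 splits as large. The number of lists called with the preset correlation therefore does not set the real grouping apart from mixed ones, least of all for CstF-64. For probe sets called in both comparisons, 3 of 100 splits of the 9 arrays gave 23 or more. Splits that mix LPS arrays with others put the LPS effect into the spread, so that count decides nothing about the overlap, and only 20 splits keep the LPS arrays together as a treated group, too few for a share under 0.05. The highest other, 2594, took the 3 LPS arrays as the common control, as did the remaining one, 2496, which points to the structure that LPS gives the arrays.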
